A study of Homo sapiens with 10 samples.

How the data were processed

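The series compares gene expression in IMR90 human lung fibroblasts infected with an empty retroviral vector (Control, 4 samples) or with the vector carrying HRASG12V (6 samples). Per the labels' protocols, cells were grown at 3% oxygen and selected with puromycin, both cultures were kept in parallel, and RNA was taken at 80% confluence once the HRASG12V cells were senescent. RNA was extracted on a Qiagen column kit, amplified with the NuGEN WT-Ovation Pico system and labelled with biotin, per the labels' protocols. The labels number the samples within each group and do not say that they came from separate cultures or infections. The p-values therefore measure only the spread between these samples, which may be technical. Each sample is 1 array, and the number of arrays limits the precision.

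The deposited values are log2 probe set intensities made by GCRMA, per the submitters' processing notes, which give no version. No source states the log base. It was taken as log2 from the values, whose array maxima of 13.9 to 14.2 lie below the log2 of a scanner's range and above its natural log. The array distributions were nearly identical, with medians of 3.07 to 3.09. Scanner files, scan dates and any further processing by the authors are not given in the sources used here, so no test for a scan batch was made. GCRMA subtracts a background estimated from probe sequence, so values near the floor depend on that estimate. Probe sets for the never-added control transcript TrpnX averaged 1.67 in Control and 1.72 in HRASG12V samples.

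Of 54675 probe sets, 42898 were in the gene table used here, 41097 with 1 gene symbol and 1801 with several. The other 11777 were not listed there and are unnamed here, not without a gene. Entrez identifiers of 41043 single-gene probe sets matched the NCBI RefSeq gene table of the GRCh38.p14 assembly, and no symbol needed an update. That table served only for names and gene order. No coordinates are printed, since the series names no genome build. For each of 19775 genes the probe set with the highest mean over the 10 samples represented the gene, and probe sets naming several genes were not used. Of 5105 tested genes with several measured probe sets, 102 called genes had probe sets called in opposite directions.

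Genes were tested when they lay above log2 4 in at least 4 samples, which left 10047. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, on all 10 samples and without a replicate block. A gene with every sample of a group under the line has only a bound there. Its change is given as at least N-fold, the mean of the brighter group against log2 4. Below the line fitted values have no reliable order, and 131 of the genes at least 2-fold higher and 110 of those at least 2-fold lower had such a group. Such genes were tested only because samples of the other group lay above the line, so the filter fixed their direction. Gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks only whether members move on balance one way. List means and single values were compared by exact two-sided permutation over 210 splits, for which the smallest p is 0.00476. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

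The groups, the tests of genes and lists, the thresholds, the alternatives but that without _x_at probe sets, and 29 gene lists were fixed before the data were examined. The comparisons with the line for groups partly under it, and other tests said to be chosen later, were not. The lists cover RAS-ERK feedback, cell cycle inhibitors with the retinoblastoma family, DNA damage checkpoint targets, secreted cytokines, secreted proteases and growth factors, NF-kB targets, TGF-beta and Notch, DNA replication, nucleotide synthesis, mitosis, DNA repair, heterochromatin and lamina, replicative histones, histone variants, lysosome and autophagy, the unfolded protein response, cholesterol synthesis, interferon-stimulated genes, extracellular matrix, contractile genes, the Wnt pathway, glycolysis and hypoxia, ribosome biogenesis, immediate early and heat shock genes, housekeeping genes, and markers of fibroblasts, epithelial cells, endothelial cells and leukocytes. Of these, 28 had members above the line, and 6 genes stood in more than 1 list. Genes named by rule were HRAS, the 12 largest increases and 12 largest decreases among called genes whose groups did not overlap, up to 4 called members per list with the largest change, and a short fixed set of senescence genes. Other list members named with a value, such as CCL20, MMP1, COL3A1 and FN1, were chosen after their values were seen. Some genes of the fixed set and lists were not analysed here.

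The limma and camera steps were tested on simulated data for the same comparison, with 10047 genes of which 50 per size were changed. Recovery was 26% at a log2 change of 0.25, 80% at 0.5, 98% at 1 and 100% at 2, and 2.56% of the 156 calls were false. With no list changed 0 lists were called, and 10 of 10 shifted lists were called. The genes were simulated independently of each other, so this does not test list calls when members move together between samples. The changed genes were also a far smaller share than the 60.7% of tested genes called in the data. Alternatives covered the filter, normalization, a constant of 16 added before logs, the choice of probe sets, the variance model, array weights, the replicate block, leaving out each sample, HRASG12V replicates 1 to 4 alone and the list tests. An average over the probe sets of a gene took in those under the line, where a change can be lost.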

Results

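Messenger RNA levels were measured on Affymetrix Human Genome U133 Plus 2.0 arrays in IMR90 cells, a human diploid lung fibroblast line. The 4 Control samples came from cells infected with the empty pBABE-puro retroviral vector. The 6 HRASG12V samples came from cells infected with the same vector carrying HRASG12V, an activated form of the small GTPase HRAS, and harvested after they had entered senescence. The comparison addressed how gene expression differs once oncogene-induced senescence is established. The array medians lay between 3.07 and 3.09 on the log2 scale in all 10 samples, and 10047 genes lay above the background line. Values below are mean log2 intensity ± SD, and log2 fold changes are HRASG12V minus Control.

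HRAS itself was higher in the HRASG12V samples, at 8.55 ± 0.20 (n = 6) against 7.38 ± 0.15 (n = 4). The log2 fold change of 1.18 (SE 0.106) corresponded to 2.26-fold and was present in 6 of 6 samples. An exact two-sided permutation test gave p = 0.00476, the smallest that 4 against 6 samples allow. The array held 1 HRAS probe set, and whether it lies within the delivered sequence is not given in the sources used here.

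In the HRASG12V cells 17 of 21 RAS-ERK feedback genes rose and all 34 measured mitotic genes fell, with a median log2 fold change of -1.37 for the mitotic genes. The camera calls of these lists held at adjusted p = 0.0265 each with an estimated correlation. Of the 32 extracellular matrix genes 28 fell, and of the 21 measured members of the senescence-associated cytokine list 17 rose and 4 fell. The camera calls of these lists were lost at adjusted p = 0.0547 and 0.457 with an estimated correlation. The chemokine receptor CXCR4 and the protease inhibitor PI3 showed the largest increases, from near or below the background line to log2 11.10 ± 0.05 and 11.27 ± 0.10 (n = 6). At the level of single genes, 3292 were higher and 2805 lower in HRASG12V by limma at an adjusted p under 0.05. Of these, 479 were at least 2-fold higher and 654 at least 2-fold lower. The groups did not overlap for 4773 genes, 47.5% of those tested, where chance gives 0.952%. Correlations within Control and within HRASG12V were 0.996 to 0.997 across probe sets of sample pairs, and those between groups were 0.978 to 0.983. Of 28 lists camera called 3 higher and 8 lower, and with an estimated correlation 1 and 2. The correlations are across genes, which are not independent replicates.

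**Figure D1:**
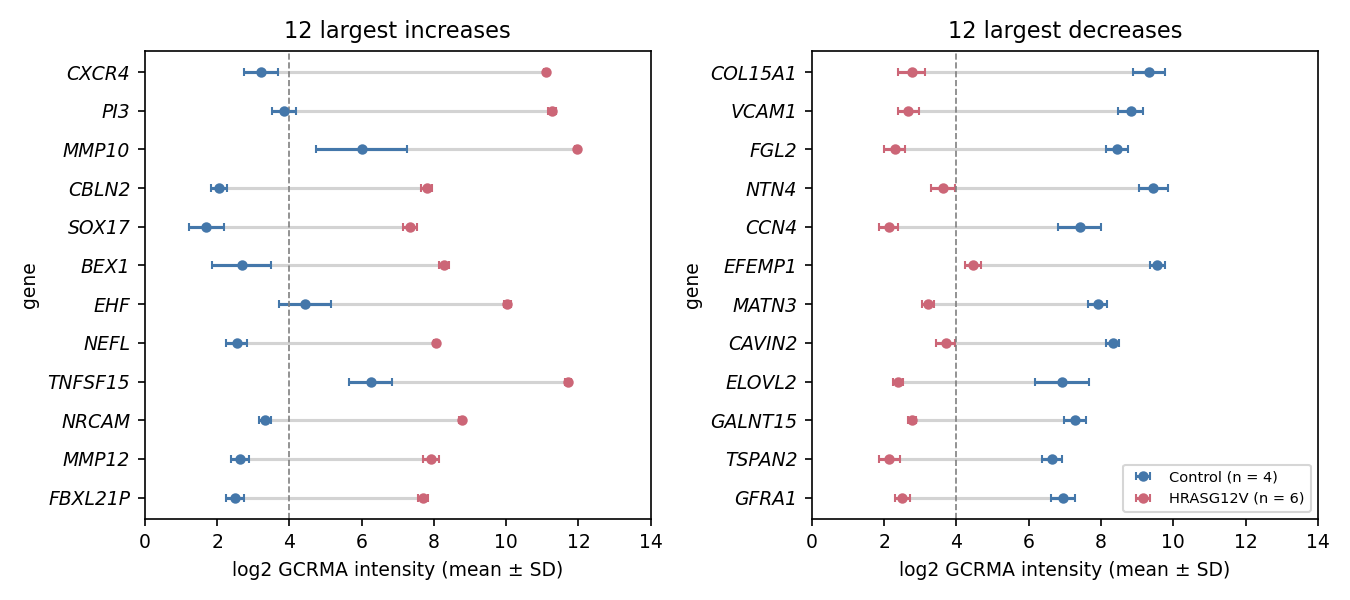
Mean log2 GCRMA intensity ± SD of the 12 genes with the largest fitted increases (left) and decreases (right), in Control (blue, n = 4) and HRASG12V (red, n = 6) samples. The dashed line is the background line at log2 4; most of these genes lay under it in 1 of the groups, so their folds are lower bounds.

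The 12 genes with the largest fitted increases were ordered partly on Control values under the line, which have no reliable order. COL10A1 and GABRA2, at least 21.8-fold and 20.2-fold higher, and CSF3 and CNIH3, 22.9-fold and 18.8-fold higher, lay outside the 12. Some of the 12 had smaller bounds. PI3 (elafin) rose 171-fold by fitted values and 154-fold against the line, with 3 of its 4 Control samples under it. The stromelysin MMP10 rose 61.9-fold, the epithelial transcription factor EHF 48.2-fold and the cytokine TNFSF15 44.0-fold. MMP10 varied widely among Control samples, at 6.00 ± 1.27 (n = 4), and was uniform in HRASG12V, at 11.95 ± 0.04 (n = 6). For the other 8 genes every Control sample lay under the line, so the increase was a lower bound. CXCR4 was at least 137-fold higher. The cell adhesion molecule NRCAM was at least 27.2-fold higher, BEX1 at least 19.5-fold and the neurofilament gene NEFL at least 16.5-fold. The macrophage elastase MMP12 was at least 15.1-fold higher, the synaptic organiser CBLN2 at least 13.9-fold, FBXL21P at least 12.9-fold and the transcription factor SOX17 at least 10.1-fold. These bounds hold for the 1 probe set used per gene. With all probe sets of a gene averaged, the log2 fold changes of CXCR4, NRCAM, NEFL and FBXL21P were 6.04, 4.36, 2.98 and 3.36, each under its bound. Adjusted p values from limma for these 12 genes ran from 2.39e-14 for NRCAM to 2.67e-08 for MMP10.

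The 12 genes with the largest fitted decreases were ordered partly on HRASG12V values under the line. AQP3 and RGCC, 20.5-fold and 18.5-fold lower, lay outside the 12, and some of the 12 had smaller bounds. The fibulin EFEMP1 fell 34.3-fold. The caveolar protein CAVIN2 fell 24.5-fold by fitted values and 20-fold against the line, with 5 of its 6 HRASG12V samples under it. The other 10 lay under the line in every HRASG12V sample. The laminin-binding netrin NTN4 was at least 43.6-fold lower, the basement membrane collagen COL15A1 at least 40.2-fold and the adhesion molecule VCAM1 at least 28.2-fold. FGL2 was at least 21.7-fold lower, the matrilin MATN3 at least 15.0-fold, the matricellular CCN4 at least 10.6-fold and GALNT15 at least 9.67-fold. The GDNF co-receptor GFRA1 was at least 7.74-fold lower, the fatty acid elongase ELOVL2 at least 7.59-fold and TSPAN2 at least 6.23-fold. Adjusted p values from limma ran from 1.16e-12 for EFEMP1 to 3.32e-09 for ELOVL2.

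Feedback regulators of RAS-ERK signalling moved up as a group: 17 of 21 measured members rose, 2 fell and 2 did not pass, and the counts were the same adjusted over the list alone. The ERK pathway inhibitors SPRY2 and SPRY4 rose by log2 3.07 and 2.68, and the ERK phosphatases DUSP5 and DUSP6 by 2.48 and 1.98. SPRY1 and the receptor EPHA4 fell by 1.54 and 1.61. The camera test placed the list above other genes (adjusted p = 8.26e-05), and this call held at adjusted p = 0.0265 with an estimated correlation. CCND1 was at 11.88 ± 0.07 (n = 4) and 11.96 ± 0.05 (n = 6) and did not pass limma's test (adjusted p = 0.277). HMGA1 rose by log2 0.36.

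Secreted cytokines and chemokines changed in both directions, with 17 of 21 measured members higher and 4 lower, both over all genes and adjusted over the list alone. The list also holds the receptor IL13RA2, which was higher. Granulocyte colony-stimulating factor CSF3 rose by log2 4.52, IL24 by 4.00, IL1A by 3.81 and CCL20 by 3.30. CSF3 varied widely among Control samples, at 5.94 ± 1.45 (n = 4), and its change was 3.86 without Control replicate 2. The interleukin-1 receptor antagonist IL1RN was at least 1.97-fold higher. IL1B rose from 11.12 ± 0.40 (n = 4) to 12.82 ± 0.07 (n = 6), a log2 fold change of 1.70. IL6 and CXCL8 rose by smaller amounts from high Control levels, IL6 from 11.58 ± 0.31 to 12.18 ± 0.11 and CXCL8 from 12.61 ± 0.29 to 13.28 ± 0.05. Probe sets this bright gave smaller folds than dimmer probe sets of the same gene, by a median of 0.55 log2 over 29 genes chosen on the bright probe set. The 2 probe sets of CXCL8, both bright, went the other way, at 0.59 for the dimmer and 0.67 for the brighter. The chemokine CXCL12, the ligand of CXCR4, was at least 5.8-fold lower, and CCL2 and TSLP fell by 1.14 and 1.09. The list median was 1.18, or 1.13 with genes under the line set at their bound, and camera called it higher (adjusted p = 0.00177), a call lost at adjusted p = 0.457 with an estimated correlation. The list mean was 8.44 ± 0.38 in Control and 9.70 ± 0.02 in HRASG12V (exact permutation p = 0.00476), and the Control samples spread from 7.93 to 8.85. With all probe sets of a gene averaged, the log2 fold change of IL1A was 1.96, but only 1 of its probe sets was measured above the line.

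Secreted proteases and growth factors had 15 of 27 members higher and 10 lower, or 16 and 10 adjusted over the list alone. The matrix metalloproteinases MMP10 and MMP12 led the increases, followed by BMP2 at log2 3.65 and ANGPTL4 at 2.93 (1.82 with its probe sets averaged). MMP3 rose by 2.17 and MMP1 by 1.43, and MMP9 was at least 3.39-fold higher. Hepatocyte growth factor HGF and IGFBP6 fell by 1.69 and 1.45. Camera did not call this list (adjusted p = 0.225). NF-kB pathway targets had 10 of 15 members higher and 3 lower, also adjusted over the list alone. IRAK2 rose by 1.14 (0.68 with its probe sets averaged), the inhibitor NFKBIA by 0.93 and ICAM1 by 0.82. Their median was 0.56 and their mean 0.00, with VCAM1 far lower, and camera did not call the list (adjusted p = 0.130).

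**Figure D2:**
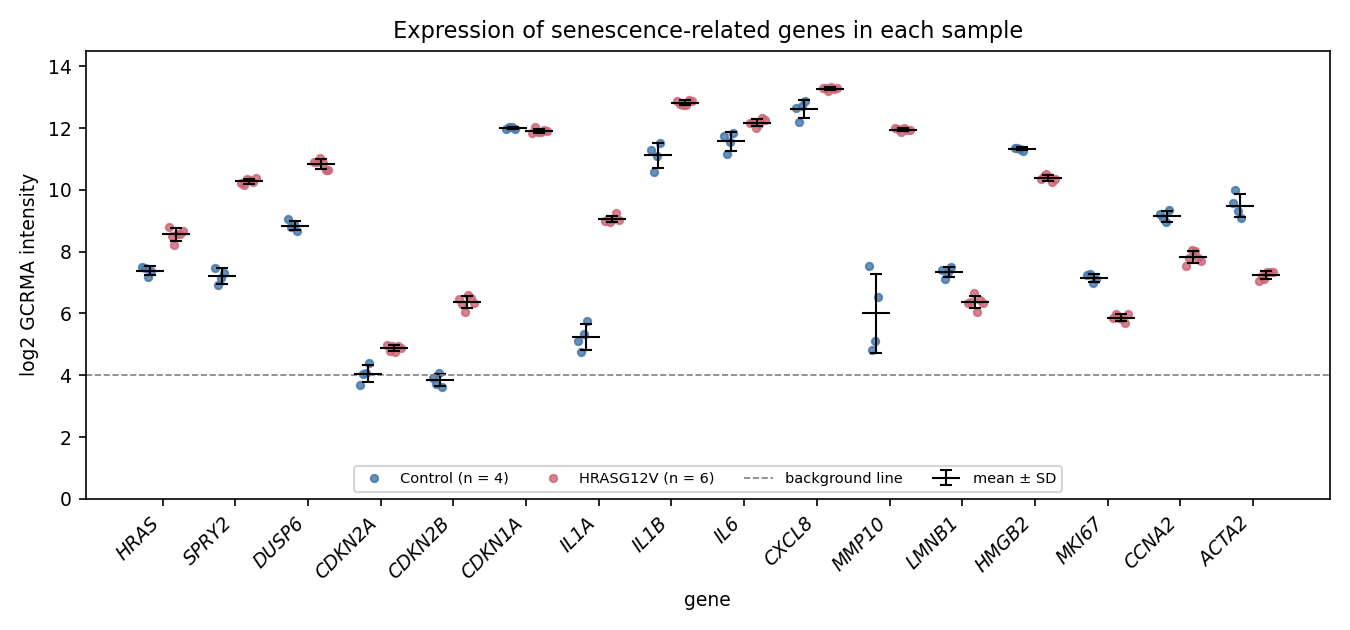
Log2 GCRMA intensity of senescence-related genes in each Control (blue, n = 4) and HRASG12V (red, n = 6) sample, with mean ± SD and the background line at log2 4 (dashed). IL1A, CDKN2B and SPRY2 were higher in every HRASG12V sample than in any Control sample, LMNB1, MKI67 and ACTA2 were lower, and CDKN1A differed by -0.09.

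Cell cycle inhibitors moved apart. CDKN2B, which encodes the inhibitor p15, rose from 3.84 ± 0.20 (n = 4), with 3 of 4 samples under the line, to 6.38 ± 0.19 (n = 6). CDKN2A, the locus of p16 and ARF, rose from 4.05 ± 0.29 to 4.88 ± 0.10, close to the background line. Its only measured probe set is of the _x_at type, prone to cross-hybridise, so no value without that type was had. CDKN1A, which encodes p21, was at 11.91 ± 0.07 in HRASG12V, differed from Control by -0.09 and did not pass limma's test (adjusted p = 0.217). Its probe set was about as bright as those of IL6. The retinoblastoma relative RBL1 fell by 1.16, CDKN1C by 0.97 and RB1 by 0.23, the last with a call lost without Control replicate 4 (limma adjusted p = 0.0501) and with HRASG12V replicates 1 to 4 only (0.0628). In all, 2 of the 8 measured inhibitors and retinoblastoma family members were higher and 4 lower, also adjusted over the list alone. The list median was -0.18 and its mean 0.04, and camera did not call it (adjusted p = 0.441). With all probe sets averaged, the log2 fold change of CDKN2B was 1.43 and that of RBL1 -0.64. With 16 added before taking logs, that of CDKN2A was 0.48 and that of CDKN1C -0.52.

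The list named DNA damage checkpoint targets holds direct targets of the p53 transcription factor. They were lower in the HRASG12V cells: 13 of 23 fell and 4 rose, or 14 and 4 adjusted over the list alone. The death receptor FAS fell by log2 1.43, SESN1 by 1.42, SPATA18 by 1.20 and PHLDA3 by 0.83. GDF15 rose by 0.55, PLK3 by 0.42, AEN by 0.35 and TIGAR by 0.19. Camera called the list lower (adjusted p = 0.00984), a call lost at adjusted p = 0.110 with an estimated correlation.

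Mitotic genes fell without exception, 34 of 34 over all genes and adjusted over the list alone, and 26 of them at least 2-fold. The mitotic kinesin KIF20A fell by log2 2.36, DLGAP5 by 2.17, the cytokinesis factors ANLN and PRC1 by 1.98 and 1.79, and the proliferation marker MKI67 by 1.29. Camera called the list lower (adjusted p = 5.38e-17), and the call held at adjusted p = 0.0265 with an estimated correlation. DNA replication genes had 21 of 29 members lower and 3 higher, also adjusted over the list alone, and a median of -0.37. Cyclin A, CCNA2, fell by 1.33, the helicase subunit MCM6 by 1.05, GINS2 by 0.91, PCNA by 0.88 and E2F1 by 0.31, whereas cyclin E, CCNE1, rose by 0.73. Camera called replication genes lower (adjusted p = 0.0011), lost at adjusted p = 0.151 with an estimated correlation. Of the 14 measured DNA repair genes, 10 fell and none rose, or 10 and 1 adjusted over the list alone. BRIP1 was at least 2.07-fold lower, and BARD1, FANCB and RAD51AP1 fell by 1.06, 1.00 and 0.98. With 16 added BARD1 was at -0.68. Camera called repair genes lower (adjusted p = 0.00177), lost at adjusted p = 0.0547 with an estimated correlation. Nucleotide synthesis genes had 7 of 22 members higher and 10 lower, the same adjusted over the list alone, and were not called (camera adjusted p = 0.382). TK1 fell by 1.45, TYMS by 1.17 and the ribonucleotide reductase subunit RRM2 by 0.53, whereas CTPS1 rose by 0.73 and SHMT1 was at least 1.29-fold lower.

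Nuclear lamina and heterochromatin factors had 10 of 27 members lower and 4 higher, or 10 and 3 adjusted over the list alone. The lamin LMNB1 fell by log2 0.98, HMGB2 and the helicase HELLS by 0.94 each, while HMGA2 rose by 0.41. EZH2, the methyltransferase of the Polycomb complex, was at 5.76 ± 0.23 (n = 4) and 5.69 ± 0.08 (n = 6) and did not pass limma's test (adjusted p = 0.591). With all probe sets averaged, HMGB2 was at -0.41, HELLS at -0.47 and HMGA2 at 0.93. Camera did not call the list (adjusted p = 0.144). Replication-dependent histone genes had 3 of 11 members higher and 5 lower, also adjusted over the list alone. H1-2 fell by 1.36 and H2AC8 by 1.05. H2BC4 was at least 1.72-fold higher. Their median was 0.05, their mean -0.13 and the camera direction lower (adjusted p = 0.477). Of the 7 histone variants, 5 fell and none rose, also adjusted over the list alone, led by H2AJ at -0.91 and H2AZ2 at -0.41, and camera did not call them (adjusted p = 0.145). The averaged probe sets of H2AJ gave -0.32, and only 1 of its 3 measured probe sets was called lower.

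**Figure D3:**
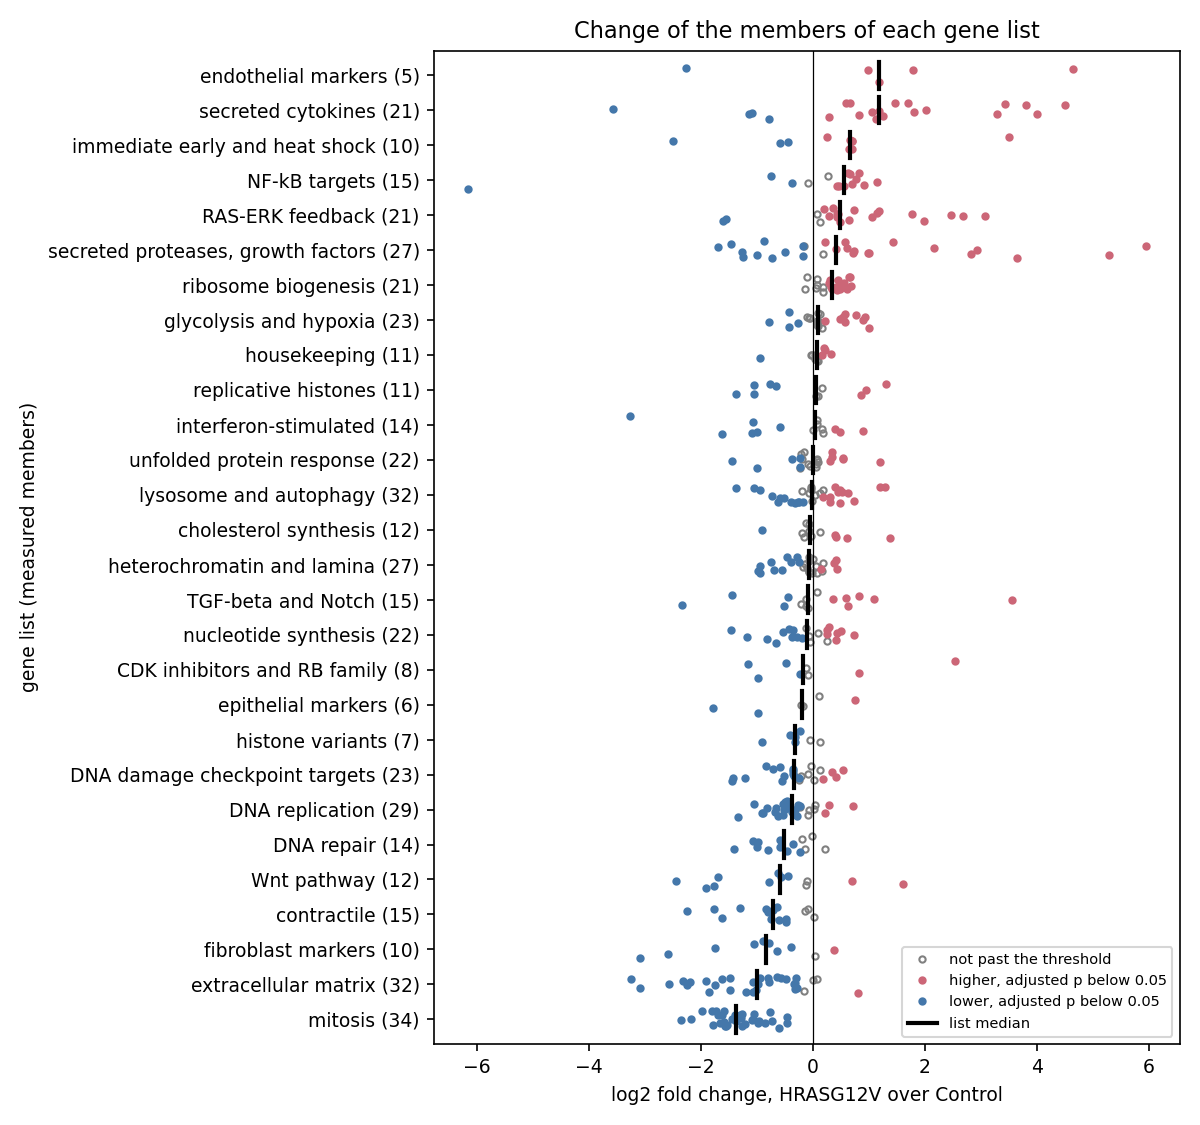
Log2 fold change, HRASG12V over Control, of every measured member of 28 gene lists (members in brackets), coloured by direction where limma's adjusted p was under 0.05, with the list median as a bar. All 34 mitotic genes lie left of 0, and 17 of the 21 members of the cytokine list lie right of it.

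Extracellular matrix genes fell broadly: 28 of 32 were lower, 16 of them at least 2-fold, and 1 was higher, the same adjusted over the list alone. Fibulin FBLN1 fell by log2 3.24, lumican LUM by 3.08, the basement membrane collagen COL4A1 by 2.56, fibrillin FBN2 by 2.31 and COL3A1 by 1.86. The proteoglycan BGN rose by 0.81, and fibronectin FN1 was at 12.51 ± 0.03 (n = 4) and 12.51 ± 0.04 (n = 6). A probe set this bright may understate a change, as described for IL6 and CXCL8. Camera called the list lower (adjusted p = 8.80e-12), lost at adjusted p = 0.0547 with an estimated correlation. With all probe sets averaged FBLN1 was at -1.31, LUM at -2.0 and FBN2 at -1.04. Contractile genes had 12 of 15 members lower and none higher, also adjusted over the list alone. Smooth muscle actin ACTA2 fell by 2.25, TAGLN by 1.77 and MYH10 by 1.63, and CNN1 was at least 1.36-fold lower. Camera called them lower (adjusted p = 1.01e-05), lost at adjusted p = 0.156 with an estimated correlation. The averaged probe sets of ACTA2 gave -1.09. Fibroblast markers had 8 of 10 members lower and 1 higher, also adjusted over the list alone, and 4 of them are matrix genes already counted. THY1 fell by 2.59, DCN by 1.75 and PDGFRB by 1.05, and FAP rose by 0.38. Vimentin VIM, about as bright as FN1, was at 12.39 ± 0.06 and 12.43 ± 0.11. Camera called the markers lower (adjusted p = 0.000748), and the call held at adjusted p = 0.0374 with an estimated correlation.

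Wnt pathway genes had 8 of 12 members lower and 2 higher, also adjusted over the list alone. The receptors FZD7 and FZD2 fell by log2 2.45 and 1.70, the ligand WNT16 by 1.90 and the antagonist DKK1 by 1.77, and the transcription factor LEF1 was at least 1.26-fold higher. Camera called the list lower (adjusted p = 0.00515), lost at adjusted p = 0.0547 with an estimated correlation. Without probe sets of the cross-hybridising _x_at type WNT16 was at -1.04, and with 16 added FZD2 was at -1.02. TGF-beta and Notch genes had 6 of 15 members higher and 4 lower, or 6 and 5 adjusted over the list alone. The Notch target HEY1 rose by 3.55, SMAD7 2.15-fold and NOTCH1 by 0.63 (0.41 with its probe sets averaged), whereas TGFB2 fell by 2.33 and CCN2 by 1.43. Their median was -0.08 and mean 0.13, and camera did not call them (adjusted p = 0.927).

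Ribosome biogenesis factors rose by small amounts, 14 of 21 higher and none lower, also adjusted over the list alone. POLR1C rose by log2 0.68, NOP14 by 0.67, RRP12 by 0.65 and MYC by 0.62. RRP12 was at 0.21 with its probe sets averaged, and NOP14 at 0.45 with 16 added. Camera called the list higher (adjusted p = 0.00515), lost at adjusted p = 0.0730 with an estimated correlation. Immediate early and heat shock genes had 7 of 10 members higher and 3 lower, also adjusted over the list alone, and were not called (camera adjusted p = 0.164). EGR3 was at least 6.99-fold higher and EGR1 and IER2 rose by 0.70 each, whereas KLF4 fell by 2.50. Glycolysis and hypoxia genes had 9 of 23 members higher and 4 lower, also adjusted over the list alone, and were not called (camera adjusted p = 0.178). The hexokinases HK2 and HK1 rose by 1.01 and 0.90 and the glucose transporter SLC2A1 fell by 0.77. Of the 2 measured probe sets of HK2 only 1 was called higher, and the dimmer one was at -0.22. The averaged probe sets of HK2 gave 0.25.

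Other lists moved in both directions and none of them was called by camera. Lysosome and autophagy genes had 12 of 32 members higher and 12 lower (camera adjusted p = 0.891), with NPC1 up by log2 1.28 (0.48 with its probe sets averaged), GLA up by 1.21, the cathepsin CTSK at -1.05 and FUCA1 at least 1.51-fold lower. The unfolded protein and stress response had 6 of 22 members higher and 5 lower (camera adjusted p = 0.910). PPP1R15A rose by 1.20 and ASNS fell by 1.44 (-0.71 with its probe sets averaged), and the list median of 0.01 and mean of -0.02 differed in sign. Cholesterol synthesis genes had 4 of 12 members higher and 1 lower (camera adjusted p = 0.678), with INSIG1 up by 1.38 and SC5D at -0.91, a median of -0.05 and a mean of 0.12. Interferon-stimulated genes had 3 of 14 members higher and 6 lower (camera adjusted p = 0.338). IFIT1 was at least 6.14-fold lower and IFIT2 fell by 1.62 (-1.02 with its probe sets averaged), and the median of 0.04 and mean of -0.45 differed in sign. Housekeeping genes had 4 of 11 members higher and 1 lower (camera adjusted p = 0.678), with GUSB at -0.94 and HPRT1 at 0.34, or 0.18 with its probe sets averaged. Counts adjusted over the list alone were the same for these 5 lists.

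Markers of other cell types were mostly under the background line. None of the 12 leukocyte markers on the array lay above it. Of 6 measured epithelial markers, KRT19 fell by log2 1.77, EPCAM was at least 1.65-fold lower and CLDN4 at least 1.26-fold higher (list camera adjusted p = 0.441). Of 5 measured endothelial markers, 4 rose and TEK fell by 2.26, with TIE1 at least 7.85-fold and ESAM at least 1.22-fold higher, ROBO4 up by 1.18 and PECAM1 up by 0.98. Camera did not call the endothelial list (adjusted p = 0.0938). With probe sets averaged KRT19 was at -1.05, TIE1 at 2.47, under its bound, and ROBO4 at 0.68. Counts adjusted over each list alone were the same. Probe sets for the 3' and 5' ends of ACTB differed by 1.54 ± 0.11 log2 in Control (n = 4) and 1.73 ± 0.09 in HRASG12V (n = 6, exact permutation p = 0.00952). Those of GAPDH differed by -0.02 in both groups (exact permutation p = 0.990). The RNA was amplified before labelling, so these differences do not measure RNA integrity alone.

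Within the 6 HRASG12V samples the HRAS level was set against 4 list means. Pearson's r was -0.03 for mitosis, -0.74 for DNA replication, -0.42 for cytokines and 0.49 for RAS-ERK feedback (exact permutation p = 0.949, 0.0819, 0.417 and 0.297). Spearman's rho was -0.09, -0.66, -0.77 and 0.83 (exact permutation p = 0.919, 0.175, 0.103 and 0.0583). After Benjamini-Hochberg adjustment over the 4 relations the permutation p values were 0.328 or more for r and 0.206 or more for rho, so none passed. Without HRASG12V 3 and HRASG12V 1, the samples farthest from the median HRAS level, r was 0.75, 0.60, -0.72 and 0.86.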

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

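The tests of carried-over RNA and of array scale were chosen after the result was seen. The groups were also compared with other splits of the 10 samples into 4 and 6, of which 100 of 210 were drawn. For genes higher, lower, at least 2-fold higher and at least 2-fold lower, 1 of 100 splits, the real one, gave as many (3292, 2805, 479 and 654), and the highest of the other splits was 0 for each. At 1 of 100, this argues against a chance assignment of these samples to groups for these counts. The other splits mix the groups, which widens the spread within each, so their 0 is not a reference free of the group difference. Since nothing says that the samples came from separate cultures, a chance difference between 1 culture per group is not excluded. For gene lists higher, 48 of 100 splits gave at least the real 3, with 9 as the highest of the others, and for gene lists lower 9 of 100 gave at least the real 8, with 8 as the highest. This comparison alone does not exclude chance for the counts of lists, nor is it a reference free of the group difference. The 8 other splits with 8 lists lower all had 3 Control samples in the group of 4, and all 6 splits with 0 Control samples there gave 8 or 9 lists higher.

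Of 346 groups of 4 or 6 samples examined, 22 held a sample far from the others, where chance gives about 1 in 20, or 17.3. Of these, 7 were in Control 4, 4 in HRASG12V 3 and 4 in HRASG12V 4. In Control 4 the list means of TGF-beta and Notch (8.11), extracellular matrix (10.3) and epithelial markers (4.90) lay below the other Control samples and that of housekeeping genes (11.1) above. In the same sample FBLN1 (10.2) and KLF4 (7.19) were lower and HPRT1 (8.87) higher than in the others. In HRASG12V 3 the heterochromatin list mean (8.17), HMGA1 (11.8) and ANLN (8.92) were higher and COL4A1 (8.59) lower. In HRASG12V 4 the replicative histone list mean (6.91), CCN4 (2.65) and NSDHL (8.96) were higher and ICAM1 (10.8) lower. The endothelial list mean (5.72) and IFIT1 (2.87) were low in HRASG12V 6, VCAM1 (2.10) was low and IL1A (9.24) high in HRASG12V 5, and MATN3 (3.54) was high in HRASG12V 2. TYMS (9.96) was low in Control 2 and H2AX (7.41) high in Control 1. VCAM1, CCN4, MATN3 and IFIT1 lay below the background line in these samples.

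Among 11721 probe sets with no gene named in the table used here, the array's control probe sets left out, 1895 lay above the background line, and 73 were at least 2-fold higher and 83 at least 2-fold lower in HRASG12V. That is 8.23% of those above the line, against 11.3% of the tested genes.

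The mean of the cytokine list ranged over 0.918 log2 among Control samples, from 7.93 to 8.85, and over 0.0624 among HRASG12V samples. For the 17 risen members of the cytokine list, carried-over HRASG12V RNA would need a median share of 32.0% to lift Control 4 above Control 2. Single members needed from 1.29% (IL1RN) to 81.2% (CXCL1). At face value the 33 genes induced at least 16-fold allow a median of 4.42%, with 100% short of the needed share by more than 2-fold. Some, such as PPBP, LCE3D and HPSE, lay under the line in Control, where values have no reliable order, so they do not bound the share tightly. EHF was at 4.99 in Control 4 against a HRASG12V mean of 10.02, and TNFSF15 at 6.25 against 11.71. CXCR4 was at least 137-fold higher. These genes argue against a share as large as 32.0%. The smaller shares that some members needed are not excluded. The range of the housekeeping list among Control samples was 0.111 of that of the cytokine list. This argues only against a scale difference left in the normalized values, since the arrays had already been brought to nearly identical medians. The housekeeping list was also brighter (Control mean 10.98), where differences may be compressed, and it too was highest in Control 4 (11.05). No biological explanation was tested, since the design names no difference among the Control samples.

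IL6 and CXCL8, among the bright genes, showed small folds, 1.51-fold and 1.59-fold. Other bright genes changed more, IL1B by log2 1.70 and CCN2 by -1.43. If bright probe sets saturate, a dimmer probe set of the same gene should show the larger fold. Over 19 genes chosen on the dimmer probe set, a choice that favours it, it did so by a median of 0.860 log2 (bootstrap 95% interval 0.58 to 1.09), and over 29 genes chosen on the bright one by 0.55 (0.23 to 0.63). Saturation may therefore account for part of the small folds of bright genes. For CXCL8 the dimmer of 2 bright probe sets gave log2 0.59 and the brighter 0.67, the other way. A truly small change of IL6 and CXCL8 stays open.

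Neighbours were taken among the 10025 tested genes placed in gene order, so untested genes may lie between them. Genes at least 2-fold higher formed 63 adjacent pairs in this order, against 22.7 expected over 10000 shuffles. This argues against chance placement (permutation p = 1e-04, the smallest possible). The runs included PPBP, CXCL5, CXCL3 and CXCL2, IL1A, IL1B, IL36B, IL36RN and IL1RN, the matrix metalloproteinases MMP8, MMP10, MMP1, MMP3 and MMP12, and IFNA1, MIR31HG, IFNE and MTAP. Without probe sets prone to cross-hybridise there were 43 pairs against 17.4, and without pairs of shared symbol prefix 44 against 21.4. Neither filter alone removed the pattern. The prefix filter kept pairs of related genes such as IL1B with IL36B and PPBP with CXCL5. The filters were not combined, so the part due to gene families stays open. Genes at least 2-fold lower also lay together, in 92 pairs against 42.2. Shared regulation of neighbouring genes in the HRASG12V cells is a hypothesis that was not tested here, and transcripts that read through from one gene into the next stay open.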

How the results depend on the processing

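The setting without _x_at probe sets was chosen after seeing the data. The signs of all 141 called named genes were kept in every alternative that tested them. The counts of genes higher (3292), lower (2805), at least 2-fold higher (479) and at least 2-fold lower (654) stayed within 1.5 times in every alternative but 1: testing all probe sets gave 5885, 5316, 811 and 1235, where more features are tested. Leaving out each sample gave 3017 to 3294, 2606 to 2809, 465 to 505 and 645 to 667, with 3 lists higher and 8 lower each time. The number of lists higher was 6 with no filter, 1 with an estimated correlation and 9 with fry, against 3. The number lower was 2 with an estimated correlation and 14 with fry, against 8. The estimated correlation allows for members that move together between samples, and fry does not compare a list with other genes. EZH2, which did not pass, ranged from -0.14 without Control replicate 1 to 0.0334 without Control replicate 3 (limma adjusted p = 0.758), and the cause was not tested.

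The replicate numbers were checked for pairing. Residuals of same-numbered samples correlated at -0.018 to 0.027, against -0.072 to 0.057 for other pairs, and 1 of 4 Control samples correlated best with its own number. The check thus found no sign of pairing, but with 4 same-numbered pairs it cannot exclude it. With the replicate block, 2849 genes were higher and 2577 lower, and the list counts stayed at 3 and 8. HRASG12V 5 and HRASG12V 6, which have no same-numbered Control, were the only pair within a group whose residuals correlated positively, at 0.033. The cause was not tested. With HRASG12V replicates 1 to 4 alone, 2981 genes were higher and 2633 lower.

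Calls near the threshold were the weakest. RB1, HIRA, MACROH2A2, TBP and SDHA lost theirs in some settings (RB1 with the replicate block at limma adjusted p = 0.107), and without Control replicate 2 MACROH2A2 moved from -0.31 to -0.16. Averaging probe sets moved 27 called named genes by over 1.5 times. The average took in probe sets under the background line, so a smaller averaged fold need not come from another measured probe set. For HK2 and H2AJ, however, other measured probe sets did differ from the one used. Adding 16 also moved 27, since by construction it shrinks the folds of dim genes, where signal over background limits the fold.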

Other observations

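The tests of both lists below were chosen after the result was seen. Thrombomodulin, THBD, was at least 10.7-fold higher, the collagen COL10A1 at least 21.8-fold, the innate immune receptor TLR2 at least 8.24-fold and heparanase HPSE at least 5.37-fold. The chemokine receptor ACKR3, which like CXCR4 binds CXCL12, rose by log2 4.31 to 8.19 ± 0.16 (n = 6), from a Control mean under the line. The metallothioneins MT1F, MT1G, MT1H and MT1X rose by 1.06 to 1.15, all on probe sets of the cross-hybridising type. Among decreases, the water channel AQP3 fell by 4.36, prostacyclin synthase PTGIS by 4.03 to a mean under the line, the methyltransferase NNMT by 3.80 and pleiotrophin PTN by 3.48. These genes were chosen after their values were seen.

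Several of the largest fitted increases were genes of the epidermal barrier (PI3, EHF, LCE3D, IL36RN) or of neurons (NEFL, NRCAM, CBLN2, BEX1), and a list of each kind was written to ask whether other members rose too. Of 42 epidermal barrier genes on the array, 33 were not above the line, and 7 of the 9 measured were higher and 2 lower, DSP at -1.32 and AQP3 at -4.36. Outside the 30 largest changes each way 4 members were left, IL36B, SERPINB3, SERPINB4 and DSP. Their median lay at percentile 100 of 10000 random lists matched on mean expression. With 4 genes, of which SERPINB3 and SERPINB4 are close copies and 3 lay under the line in Control, the extent of the rise stays open. Of 21 measured neuronal genes 13 were higher and 5 lower. The 14 outside the largest changes had 6 higher and 5 lower and a median of 0.12, at percentile 78.8 of matched random lists, so their median did not stand apart from random lists. In both lists, members under the line in every Control sample, such as LCE3D and NEFL, were tested only because they lay above it in HRASG12V. The filter fixed their direction, as it did for SCG2 among decreases, so the counts of members higher are partly set by the filter.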
